A study of Mus musculus with 11 samples.

How the data were processed

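PolyA RNA of mouse ES cells (strain 129S4/SvJae) grown on irradiated mouse embryonic fibroblasts in serum and LIF was purified with RNeasy and made into libraries with the TruSeq RNA Library Prep Kit v2, per the labels' protocols. This kit keeps no strand, so that overlapping and antisense genes share reads. The 11 libraries formed 9 groups: WT (J1), TKO, TKO+Dnmt3a1 (2 libraries), TKO+Dnmt3a2 (2 libraries), TKO+Dnmt3b1, DKO, DKO+Dnmt3a1, DKO+Dnmt3a2 and DKO+Dnmt3b1. The labels do not say whether the 2 libraries of a line came from separate cultures. Reads were processed with bcl2fastq 1.8.4 and STAR 2.4.0 on build mm9, per the submitters' processing notes. The deposited values were RPKM, made by the authors, for 24016 genes with 1 RefSeq transcript each and 3 decimals. The counting tool, the gene lengths used, the strand setting and the treatment of duplicates were not stated. RPKM sums ran from 380927 to 422189 per library. No symbol was duplicated, and 3140 genes were listed at 0 in every library. The table held 0 other per-sample columns.

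Read depth is not given in the file and was estimated from the spacing of the RPKM values: for transcripts of up to 400 nt, the total was sought at which the most values corresponded to whole reads of up to 5 within 0.05. In M reads it came to 32.38 (WT), 25.82 (TKO), 22.36 and 32.78 (TKO+Dnmt3a1), 22.7 and 26.9 (TKO+Dnmt3a2), 21.76 (TKO+Dnmt3b1), 29.46 (DKO), 24.8 (DKO+Dnmt3a1), 28.44 (DKO+Dnmt3a2) and 32.52 (DKO+Dnmt3b1). At these totals 86.3% to 91.6% of values were whole, against a median of 1.7% to 4.1% at other totals. At the lowest depth 1 read in a transcript of 2 kb is 0.023 RPKM and 10 reads are 0.23 RPKM. From 11805 (DKO+Dnmt3a2) to 12936 (TKO+Dnmt3b1) genes were at 1 RPKM or more.

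Values were taken as log2(RPKM + 0.5), without further scaling, and the 14229 genes at 1 RPKM or more in at least 1 library were tested. The pseudocount makes fold changes of low genes smaller than those of the RPKM values, and a gene listed at 0 in an arm is given without a fold. Linear models were fitted with limma 3.58.1 (lmFit, eBayes with a trend) in R 4.3.3, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. The unit was RPKM and not counts, and the authors' gene lengths are not in the file, so that the count test named in the design for count data was not used. There were 13 comparisons. For 10 of them all 11 libraries were fitted with 9 group means, leaving 2 residual degrees of freedom and a prior of 3.7, so that libraries without a replicate were assumed to vary like the 2 replicated lines. For 3 of them (any enzyme put back against the parent line, TKO family against DKO family, Dnmt3b1 against Dnmt3a) the 10 libraries other than WT were fitted with family and add-back as additive terms, leaving 5 residual degrees of freedom and a prior of 3.79. In the fit of 9 group means, p-values measure only the spread between the 2 libraries of TKO+Dnmt3a1 and of TKO+Dnmt3a2, and none between lines. In the additive fit they measure only the spread between these libraries and lines. A line stands for its genotype, so that clonal differences cannot be separated from genotype. The comparisons, lists, naming rule and all alternatives except those said below to be added were fixed before the data were examined.

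There were 16 gene lists: germline genes with promoters methylated in somatic and ES cells (39 of 44 members tested), 2-cell-like state (21 of 24), naive pluripotency (24 of 24), primed and formative epiblast (19 of 20), primitive and definitive endoderm (18 of 23), mesoderm and primitive streak (12 of 22), neural ectoderm (12 of 20), trophoblast (17 of 24), imprinted genes (38 of 45), Hox genes (28 of 39), X-linked Rhox, Xlr and Mage genes (20 of 35), Polycomb complex subunits (30 of 30), interferon-stimulated genes (31 of 32), p53 targets (21 of 21), fibroblast markers (30 of 30), and Tet genes, base excision and methyl-CpG readers (20 of 20). Lists of macrophage markers (18 of 18) and Y-linked genes (6 of 8) were added after the data were seen. They were tested with fry of limma, adjusted over the 16 lists in each comparison, with the added lists unadjusted. Fry asks whether the members move in 1 direction and makes no comparison with other genes. Camera, which makes that comparison, was run with a preset correlation of 0.01 and with an estimated correlation. Median changes were set against 10000 random lists matched on mean expression in 20 bins. Close copies (Zscan4, Usp17l, Tdpoz, Xlr3, Rhox, Lce1 and Mir1906 genes) share reads, and their single values are uncertain.

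Genes were named by a fixed rule. Of called genes at 1 RPKM or more in an arm, without a predicted or clone name, the 10 largest rises and 10 largest falls were named in TKO against WT, DKO against WT and any add-back against the parent line, and 5 and 5 in the other comparisons. With fewer than 5 calls in a direction, the largest uncalled changes were named as such. The 4 members of each list with the largest changes were named too, with the Dnmt, Uhrf1 and Tet genes. Some genes that the rule selects are not reported here. Any other list member named beside a count was chosen after its values were seen. Reversal across families was described against 10000 matched random sets, and agreement of the knockouts against 1000 simulations with a shared control. Chromosomes came from a table of a later build (GRCm38) by RefSeq accession, for 23163 genes, and chromosome medians were taken over genes with a mean of 5 RPKM or more. Genes without a match, such as H19, Xlr3a and Uba1y, had no chromosome and stayed in when chromosomes were left out.

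The fits were tested on simulated data for 14229 genes, 200 of them changed. At 2, 4 and 8 times, 19.4%, 86.6% and 92.4% were recovered in TKO against WT, 62.7%, 100% and 100% in TKO+Dnmt3a1 against TKO+Dnmt3a2, 91%, 100% and 100% in any add-back against parent line, 95.5%, 100% and 100% in TKO family against DKO family, and 85.1%, 98.5% and 100% in Dnmt3b1 add-back against Dnmt3a add-backs. Between 9 and 14 unchanged genes were called. Fry called 100 of 100 changed and 7 of 100 unchanged lists of 20 genes, for TKO family against DKO family. The simulated noise was independent between genes and libraries, with the spread of the fit of 9 group means. It held no spread between lines and no correlation between genes, so that recovery and false calls can be worse in the real data. Alternatives were pseudocounts of 0.1 and 1, no filter and a stricter filter, quantile normalization, median ratio scaling, a prior without trend, a robust prior, a minimum log2 change of 1, the other model, each line counted once, the replicate number as a block, and leaving out each library in turn. Added after the data were seen were leaving out both Dnmt3b1 libraries, the fibroblast mean as a covariate, removal of chromosome medians, leaving out chromosomes 6, 8, 11, 12, 16 and Y, and list tests in further comparisons. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.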

Results

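RNA-seq had been done on 11 libraries of mouse embryonic stem (ES) cells grown on irradiated mouse embryonic fibroblasts with LIF and serum. The wild-type (WT) line was J1. The TKO line lacked the DNA methyltransferases Dnmt1, Dnmt3a and Dnmt3b, and the DKO line lacked Dnmt3a and Dnmt3b only. Dnmt1 copies methylation to the new strand after replication, and Dnmt3a and Dnmt3b methylate unmethylated DNA. In further lines Dnmt3a1 or Dnmt3a2 (the long and the short isoform of Dnmt3a) or Dnmt3b1 had been put back into TKO or DKO. TKO+Dnmt3a1 and TKO+Dnmt3a2 had 2 libraries each, and the other 7 groups had 1. The deposited table gave RPKM for 24016 genes, of which 14229 reached 1 RPKM in at least 1 library and were tested. The depth implied by the spacing of the RPKM values was 32.4 M reads in WT, 25.8 in TKO, 22.4 and 32.8 in TKO+Dnmt3a1, 22.7 and 26.9 in TKO+Dnmt3a2, and 21.8 in TKO+Dnmt3b1. It was 29.5 M reads in DKO, 24.8 in DKO+Dnmt3a1, 28.4 in DKO+Dnmt3a2 and 32.5 in DKO+Dnmt3b1. The comparisons ask which transcripts differ without the enzymes, which differ again once an enzyme is put back, and whether either depends on Dnmt1.

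Transcripts of Dnmt1 were low in the TKO family, and those of Dnmt3a were low in the parent lines TKO and DKO. Dnmt3b was low in DKO and above WT in TKO, so that its total transcript does not check the TKO genotype. Dnmt1 stood at 71.0 RPKM in WT and at 6.73 to 12.4 RPKM in the 6 TKO family libraries, against 55.9 RPKM or more in the 4 DKO family libraries. Dnmt3a stood at 22.7 RPKM in WT, 4.24 in TKO and 3.63 in DKO. With Dnmt3a1 or Dnmt3a2 put back it reached 36.8 ± 3.64 (SD, n = 2) and 16.5 ± 7.56 (SD, n = 2) RPKM in TKO, and 17.6 and 11.4 RPKM in DKO. Dnmt3b was at 25 RPKM in WT, 45.3 in TKO and 5.68 in DKO, and at 100 RPKM in TKO+Dnmt3b1 and 29.6 in DKO+Dnmt3b1. Dnmt3l, the catalytically inactive partner of Dnmt3a and Dnmt3b, was at 97.0 RPKM in WT, at 275 RPKM or more in each TKO family library and at 140 to 252 RPKM in the DKO family. Across the 11 libraries Uhrf1, which recruits Dnmt1 to replicated DNA, lay between 88.5 and 137 RPKM, and the methylcytosine oxidases Tet1, Tet2 and Tet3 lay between 31.5 and 57.6, 9.32 and 20.7, and 1.45 and 3.88 RPKM. One value per gene cannot separate isoforms, nor a transcript left by the knockout allele from that of the enzyme put back.

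**Figure D1:**
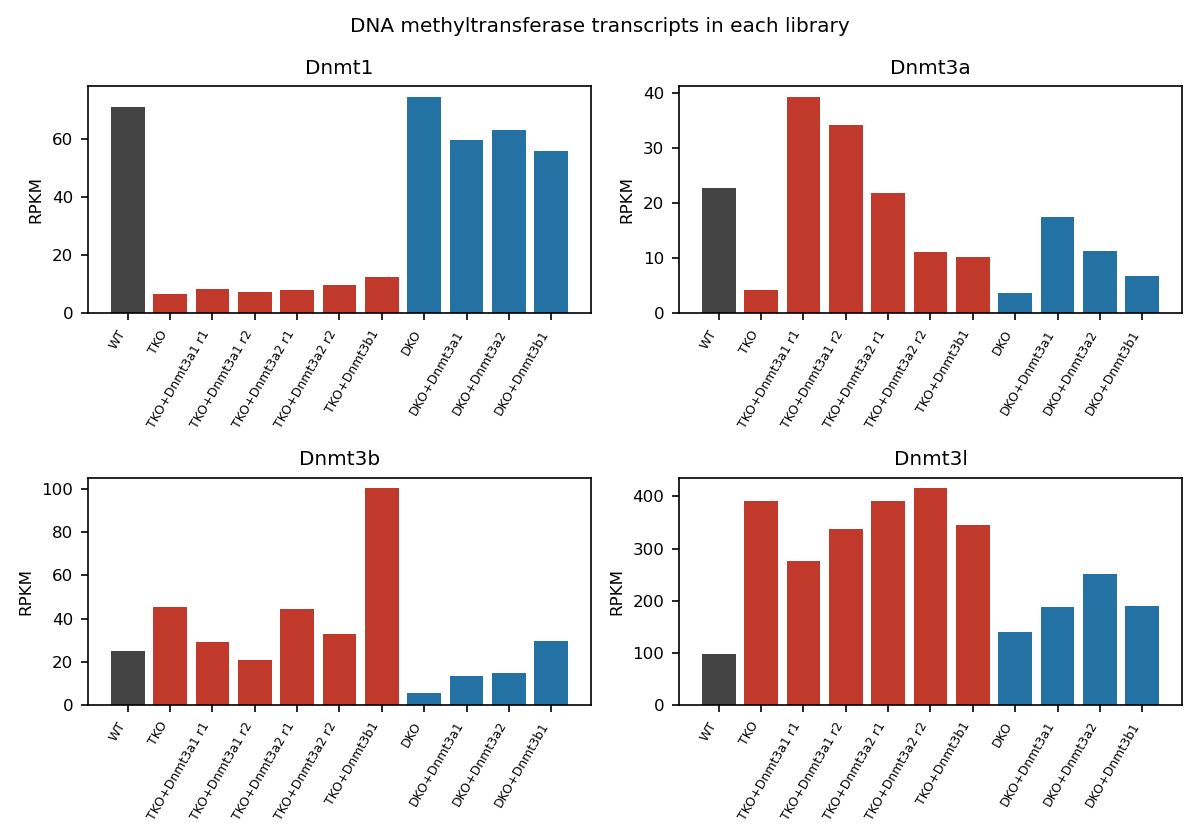
RPKM of Dnmt1, Dnmt3a, Dnmt3b and Dnmt3l, each bar 1 library of the 11. Dnmt1 is at 71.0 RPKM in WT and at or below 12.4 RPKM in the TKO family, and Dnmt3b is highest, at 100 RPKM, in TKO+Dnmt3b1.

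Replicate libraries correlated across genes at r = 0.983 (TKO+Dnmt3a1) and 0.974 (TKO+Dnmt3a2), and the lowest r between any 2 of the 11 libraries was 0.886. Both Dnmt3b1 libraries stood apart on the first principal component, which held 39.5% of the variance. These 2 libraries held the highest levels of fibroblast genes: Col1a1, a collagen of fibroblasts, was at 235 RPKM in TKO+Dnmt3b1 and 175 in DKO+Dnmt3b1, against 10.9 in DKO+Dnmt3a2 and 30.0 to 83.1 in the other 8. Lyz2, the lysozyme of macrophages, was at 193 and 180 RPKM in them and at 0.066 RPKM in DKO+Dnmt3a2. Averaged over the 30 fibroblast markers, the mean log2 value was 5.87 and 5.5 in the Dnmt3b1 libraries, 2.04 in DKO+Dnmt3a2, and between 3.13 and 4.26 elsewhere. Of the 30 markers, 24 were at 1 RPKM or more in DKO+Dnmt3a2 as well, and 1 (Dcn) also stands in the imprinted list. For the 18 macrophage markers, of which 2 reached 1 RPKM in DKO+Dnmt3a2 and 0 stand in another list, the means were 2.95 and 2.84, −0.45, and 0.51 to 1.52. The Y-linked genes Zfy1 and Uba1y were at or below 0.019 RPKM in the 7 libraries of WT and the TKO family and at 2.84 RPKM or more in the DKO family. Whole chromosomes stood apart too. The median TKO minus WT log2 difference was 0.47 on chromosome 6, 0.52 on chromosome 11, 0.47 on chromosome 16, 0.25 on chromosome 12 and 0.21 on chromosome 3, and lay within 0.08 of 0 on the others. On chromosome 11 the TKO+Dnmt3a1 replicates differed, at −0.02 and 0.34. For chromosome 8 WT and TKO were at 0.21 and 0.25, while the 5 TKO add-back libraries lay between −0.24 and −0.07.

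**Figure D2:**
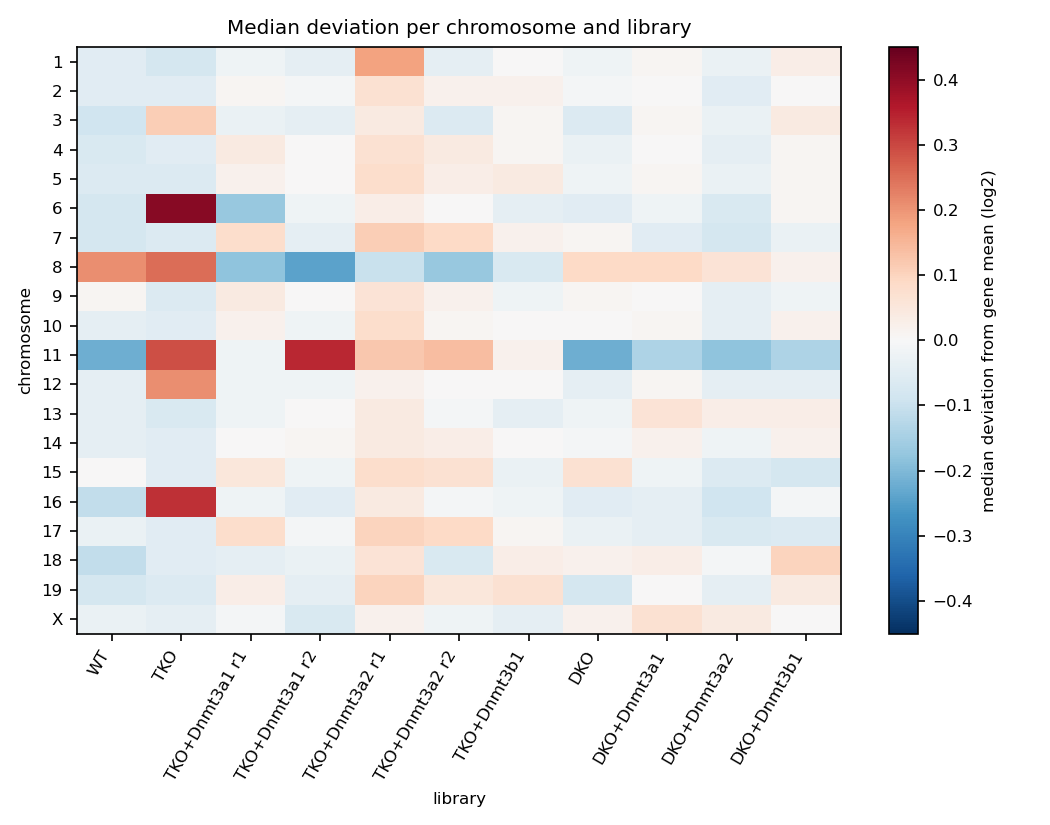
Median log2 deviation of each chromosome's genes in each of the 11 libraries, drawn as a heat map with chromosomes against libraries. TKO is higher on chromosomes 6, 11 and 16, and replicate 2 of TKO+Dnmt3a1 on chromosome 11.

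TKO against WT asks what the loss of all 3 enzymes does, with 1 library in each arm. In TKO, 37 genes rose and 12 fell. Ndufs5, a subunit of mitochondrial complex I, rose from 0.903 to 28.4 RPKM (log2 change 4.36 ± 0.23, SE), and Ube2l6, a conjugating enzyme for the ubiquitin-like protein ISG15, rose from 1.14 to 27.9 RPKM (4.11 ± 0.35). Dppa3, a gene of naive pluripotent and germ cells, rose from 11.7 to 118 RPKM (3.29 ± 0.21), and the imprinted noncoding RNA H19 rose from 29.8 to 246 RPKM (3.03 ± 0.23). Other large rises were those of Smtnl1 (3.92), Pnma5 (3.75), Tmem40 (3.47), Pramel6 (3.37), Tesc (3.29), Rhox1 (3.19) and Igll1, which was listed at 0 in WT and at 6.72 RPKM in TKO. Dnmt1 itself fell by 3.31 ± 0.24, and the epiblast genes Otx2 and Fgf15 fell by 2.90 ± 0.27 and 2.41 ± 0.27. Rps15a-ps6, a ribosomal protein pseudogene, fell by 3.72, Kbtbd11 by 3.17, Triml1 by 3.10, Bdh2 by 3.02, Alg13, a gene of protein N-glycosylation, by 2.84, Triml2 by 2.61 and Cobl by 2.44. All 49 passed limma's test at Benjamini-Hochberg adjusted p values from 0.0344 up to the threshold of 0.05, out of 2447 genes at an unadjusted p under 0.05. The median of all genes was 0.132 higher in TKO, and stood at −0.022 after quantile normalization. With quantile normalization limma called 0 genes (2245 at an unadjusted p under 0.05), and with median ratio scaling 12. Leaving out TKO+Dnmt3a1 replicate 1, TKO+Dnmt3a1 replicate 2, TKO+Dnmt3a2 replicate 1 or TKO+Dnmt3a2 replicate 2 lost every call. None of these libraries is in either arm, so that the log2 changes stayed the same and only the estimate of the spread changed. Among the genes named, Dppa3 and Tmem40 lie on chromosome 6, Kbtbd11, Triml1 and Triml2 on chromosome 8, Cobl and Rps15a-ps6 on chromosome 11 and Igll1 on chromosome 16. Without chromosomes 6, 8, 11, 12, 16 and Y, 39 genes were called, 37 of them among the 49. Bdh2 lies on chromosome 3, which was not left out.

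**Figure D3:**
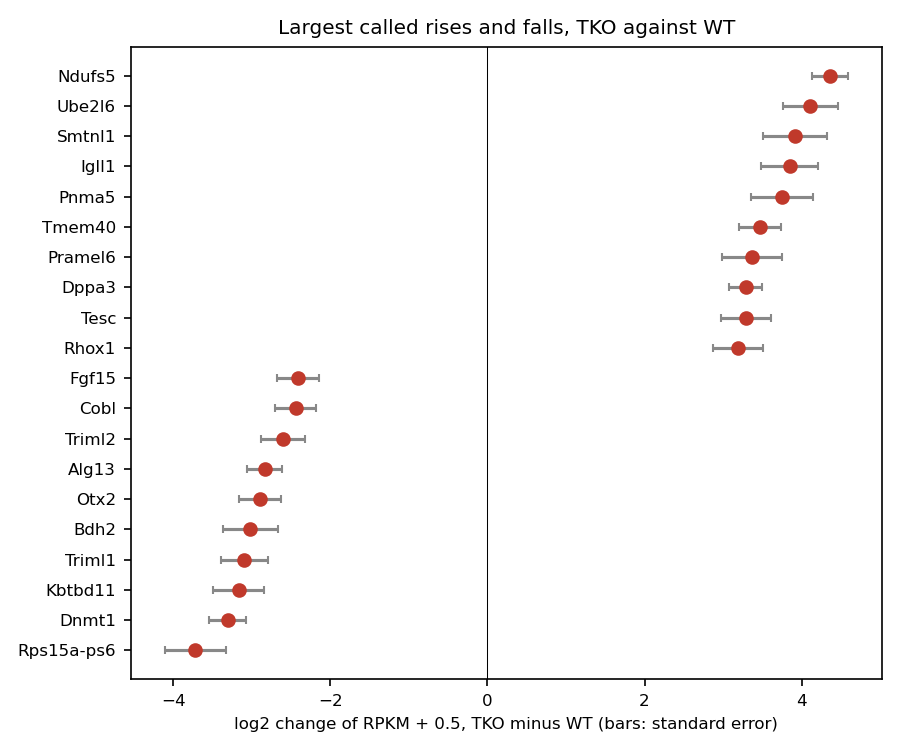
Log2 change between TKO and WT (1 library each) of the 10 largest rises and the 10 largest falls among called genes without a predicted or clone name, on the log2(RPKM + 0.5) scale with standard errors as bars. Ndufs5 is highest at 4.36 and Rps15a-ps6 lowest at −3.72.

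Among the gene lists, the X-linked Rhox, Xlr and Mage genes of the germline and placenta were higher in TKO than in WT for all 20 measured members (median 2.42). Of these, Rhox1 (3.19 ± 0.32) and Rhox6 (2.97 ± 0.24) passed over all genes, and 16 passed adjusted over the list alone. Of the 18 endoderm genes 16 were higher (median 1.52). Dab2, an endocytic adaptor of primitive endoderm, rose by 2.79 ± 0.28 and the laminin gene Lama1 by 2.28 ± 0.23, and 15 passed adjusted over the list alone. Of the 38 imprinted genes 30 were higher (median 0.52), with H19 and Grb10 (2.21 ± 0.23) called over all genes and 10 higher and 1 lower adjusted over the list alone. Genes of the 2-cell-like state were lower for 19 of 21 members (median −1.14). Zscan4a read 0.354 RPKM in TKO and 6.09 in WT, and 8 members were lower adjusted over the list alone. The germline genes Dazl (42.2 against 8.73 RPKM), Tex19.1 (99.8 against 19.2) and Asz1 (2.95 against 0.088) were higher in TKO but did not pass, nor did the naive pluripotency gene Zfp42 (47.3 against 222 RPKM), the mesoderm gene Hand1 (7.76 against 0.833) or the endoderm gene Cubn (7.61 against 0.270). Among the genes named here, Grb10, Tex19.1 and Hand1 lie on chromosome 11 and Asz1 lies on chromosome 6. The medians of these 2 chromosomes were higher in TKO by 0.52 and 0.47. The median of the imprinted list was 0.37 with quantile normalization and 0.35 with median ratio scaling. The fibroblast markers were higher for 26 of 30 (median 0.53). By fry, which tests whether a list's genes move one way on balance and does not compare them with other genes, none of the 16 lists passed, and the smallest Benjamini-Hochberg adjusted p was 0.0959 (endoderm). Median, mean and test differed in sign for the germline list (−0.07, 0.05, up), the primed list (0.31, 0, down) and the p53 list (0.10, −0.03, up). Zscan4 and Xlr members share reads with close copies, so that values of single members are uncertain.

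DKO against WT asks what the loss of Dnmt3a and Dnmt3b does while Dnmt1 is kept, again with 1 library in each arm. The X-linked list was higher in DKO for all 20 measured members (median 2.34, 15 of them adjusted over the list alone). Xlr3c read 21.5 RPKM in DKO and 0.019 in WT, Xlr3a 27.7 and 0.872, Xlr3b 7.07 and 0.019, and Xlr5c 5.72 and 0.057. The 2-cell-like list was lower for all 21 (median −1.16, 3 of them adjusted over the list alone), with Zscan4d at 0.523 against 5.94 RPKM and Zscan4c at 0.162 against 3.89. Dnmt3a (3.63 against 22.7 RPKM) and Dnmt3b (5.68 against 25) were among the 10 largest falls in value, with the homeobox gene Cdx1 (0.480 against 5.72), Cby1 (12.5 against 72.7), Bdh2 (2 against 10.4) and DQ267100, listed at 0 in DKO. The largest higher values outside the X-linked list were those of Efhc2 (17.0 against 0.742), Cox7b2 (12.3 against 0.451), Gpx2 (19.2 against 1.14), Mmp3 (23.1 against 1.61) and the Y-linked Eif2s3y (26.7 against 0.312) and Uba1y, listed at 0 in WT. Tbx3 and Klf4, transcription factors of naive pluripotency, read 7.15 against 29.8 and 27.3 against 75.9 RPKM, and the Nodal antagonists Lefty1 and Lefty2 223 against 50.7 and 154 against 21.5. Fibroblast markers were higher in DKO for 28 of 30 (median 1.01) and macrophage markers for 16 of 18 (median 0.93). None of this passed over all genes: limma called 0 genes (1181 at an unadjusted p under 0.05, smallest Benjamini-Hochberg adjusted p 0.163), and the smallest adjusted p of fry over the 16 lists was 0.221 (X-linked and mesoderm lists). Median, mean and test of the germline list differed in sign (−0.01, 0.23, up). Without the low-value filter 71 genes were called, and with an additive model over the 11 libraries 12.

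Both knockouts were compared with the same WT library. Across the 14229 genes, which are not independent replicates, the 2 sets of log2 changes correlated at r = 0.50, and unchanged groups simulated against a shared control also gave 0.50. Every simulated group had the same spread for a gene, which fixes the simulated r at 0.50 in advance. The match of the 2 values of r therefore does not show where the correlation comes from. The covariance of the 2 sets was 0.168 against a simulated 0.062, a difference of 0.106. With 0 genes called in DKO by limma, 0 calls were shared and independent lists would share 0. WT had 1 library, so the control could not be split.

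Putting an enzyme back was compared with the parent lines over both families and all 3 enzymes (8 libraries against 2). Dppa3 fell by 1.66 ± 0.12, from a mean of 89.3 to 28.4 RPKM, and the germline RNA-binding protein gene Dazl fell by 1.85 ± 0.27, from 30.4 to 10.3 RPKM. Dnmt3a rose by 1.75 ± 0.24. Of the 21 genes of the 2-cell-like state all were higher with an enzyme put back (median 1.54), and 8 passed over all genes and 18 adjusted over the list alone. Zscan4d rose by 2.64 ± 0.58, Zscan4a by 2.39 ± 0.55, Usp17lc by 1.78 ± 0.37, Zscan4b by 1.72 ± 0.39, Usp17le by 1.55 ± 0.35 and Tdpoz4 by 1.54 ± 0.35. The X-linked list was lower for all 20 members (median −1.40), with Xlr5a (fell by 2.08 ± 0.40), Magea5 and Magea8 called over all genes and 15 adjusted over the list alone. In the DKO family Xlr3a went from 27.7 RPKM in the parent to 0.871, 0.169 and 1.60 RPKM, and in the TKO family from 25.7 to between 9.09 and 24.8 RPKM. The innate immune regulator Irak3 (1.49), Sprr1a (1.52) and Lce1f (1.85) rose. Lce1f averaged 6.11 RPKM over the add-backs and read 21 RPKM in TKO+Dnmt3b1. Its close copy Lce1g averaged 16.4 RPKM with Dnmt3b1 and 0.52 with the Dnmt3a isoforms, so that a rise common to the enzymes is not shown. Gstm3, a glutathione transferase, fell by 2.52, Got1l1 by 2.16, the lactate dehydrogenase gene Ldhb by 1.77, Srrm4os by 1.75, the surrogate light chain gene Vpreb1 by 1.71, Ppp2r2c by 1.68 and the glypican gene Gpc3 by 1.65. Other list members called were the imprinted Nnat and Mcts2 and the Polycomb partner gene E130012A19Rik (1.27 ± 0.26), which rose, and the neural gene Sox3 and the p53 targets Zmat3 and Trp53inp1, which fell. The fibroblast list had a median of 0.28 (23 of 30 higher) and the macrophage list one of 0.14, and without both Dnmt3b1 libraries these medians were −0.62 and −0.63.

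In all, limma called 159 genes higher and 400 lower with an enzyme put back (28.4% higher; 4012 at an unadjusted p under 0.05), and 178 of the 559 moved by 1 or more on the log2 scale. Quantile normalization called 255 higher and 389 lower (39.6% higher) and median ratio scaling 225 and 348 (39.3%). Several named falls lie on chromosomes where TKO, 1 of the 2 parent libraries, stood higher. These are Dppa3 and Ldhb on chromosome 6, Got1l1 on 8 and Vpreb1 on 16. There the median deviation was 0.41, 0.25 and 0.33 in TKO and at most 0.03, −0.07 and 0.04 in its add-back libraries. Part of the excess of lower genes can come from this shift. The counts with chromosome medians removed or chromosomes left out, given below, were lower. The call of Dppa3 had an adjusted p of 0.00337 by limma and those of Dnmt3a and Dazl 0.0281 and 0.0290. By fry the smallest Benjamini-Hochberg adjusted p values were 0.155 (2-cell-like and X-linked lists), so that no list passed, and the median, mean and test of the imprinted list differed in sign (0.11, −0.01, up). The count rested on single libraries: it was 867 without TKO, 15 without TKO+Dnmt3a1 replicate 1, 3 without TKO+Dnmt3a1 replicate 2, 67 without TKO+Dnmt3a2 replicate 1, 2 without TKO+Dnmt3b1, 0 without DKO (limma), 2 without DKO+Dnmt3a1, 2 without DKO+Dnmt3a2 and 3 without DKO+Dnmt3b1. Dppa3 lost its call among these only without DKO, where it fell by 1.72, and Zscan4d in each of them except without TKO. With each line counted once limma called 2 genes, and with 9 group means 0 (3868 at an unadjusted p under 0.05). Without both Dnmt3b1 libraries 3 genes were called, none in the 2-cell-like list, whose median was then 0.91.

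**Figure D4:**
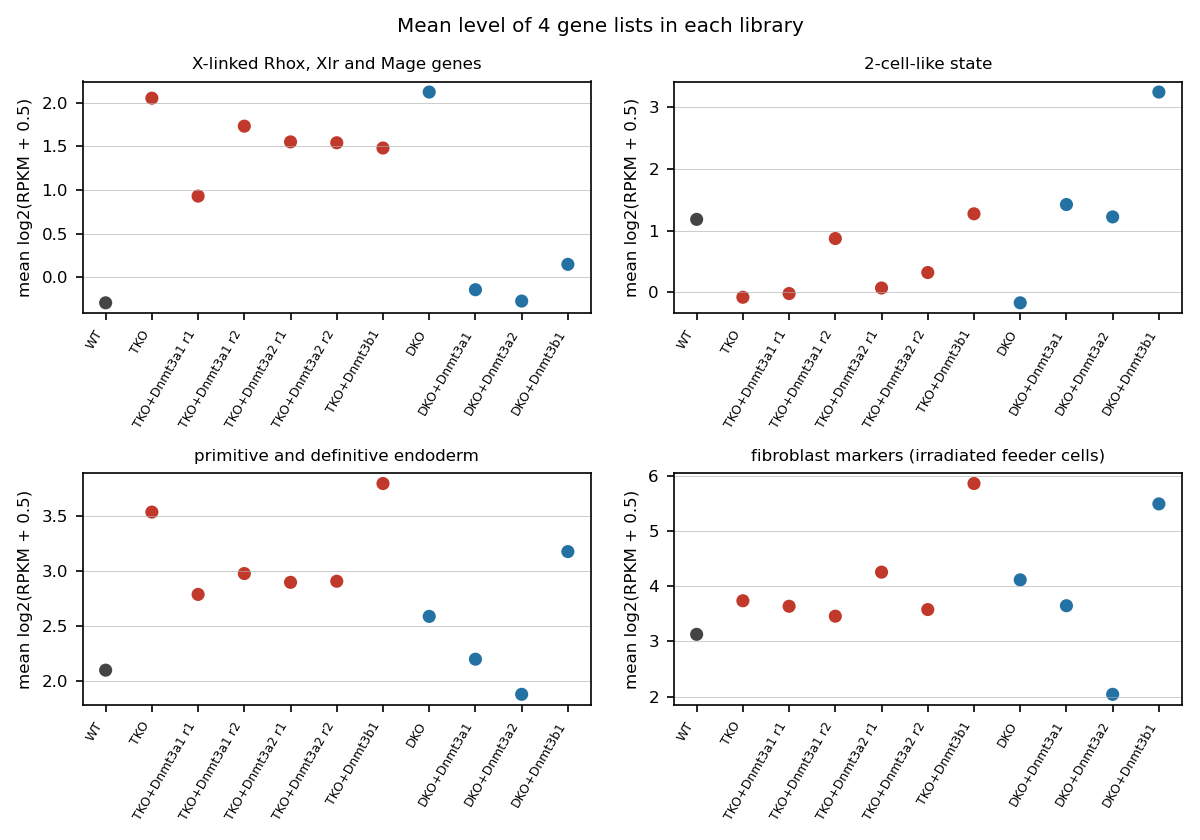
Mean log2 value of 4 gene lists (X-linked, 2-cell-like, endoderm, fibroblast) in each of the 11 libraries. The X-linked mean is 2.05 in TKO and 2.12 in DKO, −0.29 in WT, and −0.27 to 0.15 in the DKO lines with an enzyme put back.

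Each enzyme was also compared with its own parent line, where a lone library stands on at least 1 side. In DKO+Dnmt3a1 and in DKO+Dnmt3a2 4 genes each were called by limma, all of them lower. The noncoding RNA gene AF357359 of the imprinted cluster on chromosome 12 fell by 3.82 ± 0.22 with Dnmt3a1 and by 4.75 ± 0.22 with Dnmt3a2, from 45 to 2.73 and 1.19 RPKM. Rian, of the same cluster, fell by 3.44 ± 0.23 with Dnmt3a1, and read 35.1 RPKM in DKO, 2.78 and 4.48 RPKM in these lines and 102 RPKM in DKO+Dnmt3b1. Mir1906-1 and Mir1906-2, named after their values were seen, fell in both and share their reads with this region, so that the calls there are not independent. Lyz2 fell by 6.82 ± 0.27 with Dnmt3a2, from 63.3 to 0.066 RPKM, and the macrophage and fibroblast lists moved with it (medians −1.74 and −2.04, lower for 18 of 18 and 29 of 30). These lists were also lower in DKO+Dnmt3a1 (medians −0.78 and −0.55, 17 of 18 and 24 of 30) and higher in DKO+Dnmt3b1 (medians 1.29 and 1.44, 18 of 18 and 29 of 30). The X-linked list was lower for all 20 members in DKO+Dnmt3a1, DKO+Dnmt3a2 and DKO+Dnmt3b1 (medians −2.39, −2.54 and −1.93). The 2-cell-like list was higher for all 21 members in the 3 DKO lines (medians 1.16, 1.08 and 3.43, the last in DKO+Dnmt3b1). In the TKO lines its medians were 0.48 (18 of 21 higher) with Dnmt3a1, 0.32 (17 of 21) with Dnmt3a2 and 1.44 (20 of 21) with Dnmt3b1. Zscan4d read 9.97, 8.48 and 39.3 RPKM in DKO+Dnmt3a1, DKO+Dnmt3a2 and DKO+Dnmt3b1 against 0.523 in DKO. Other values of these lines were Gbx2 at 61.3 RPKM in DKO+Dnmt3a2 (7.61 in DKO), Wt1 at 9.64 in DKO+Dnmt3a1 (0.968 in DKO), and Il1rl1 and Serpinb2 at 158 and 35.8 in DKO+Dnmt3b1 (3.22 and 0.444 in DKO). Leaving out any 1 of the 4 replicated libraries gave 0 calls in DKO+Dnmt3a1 by limma. For DKO+Dnmt3a2 it gave 1 call without TKO+Dnmt3a1 replicate 1, 1 without TKO+Dnmt3a1 replicate 2, and 0 by limma without TKO+Dnmt3a2 replicate 1 or replicate 2. For DKO+Dnmt3a2 14 genes were called with a pseudocount of 0.1, 142 with a filter on the mean and 50 with a robust prior.

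In the TKO family limma called 0 genes for each enzyme put back, with 1369, 1227 and 3318 genes at an unadjusted p under 0.05 for Dnmt3a1, Dnmt3a2 and Dnmt3b1, and 0 (3873) for DKO+Dnmt3b1. The values named here did not pass. With Dnmt3a1 put back Otx2 read 7.10 RPKM (0.585 in TKO), Alg13 54.3 (8.78), Cdx1 6.93 (0.936) and Mep1b 12.8 (0.385), while Apela, a peptide hormone gene, read 5.66 (39.3), Pramel7 0.494 (4.77), Vpreb1 0.706 (6.86) and Igll1 0.222 (6.72). With Dnmt3a2 put back Dazl read 6.21 RPKM (42.2 in TKO), Timd2 0.188 (2.16), C77370 1.08 (5.83), Ephx2 14.5 (3.07) and Bnipl 6.99 (1.26). AF357425 read 2.78 RPKM with Dnmt3a2 and was listed at 0 in TKO. With Dnmt3b1 put back the growth factor gene Inhba read 136 (7.10) RPKM and the epidermal genes Lce1f, Lce1g and Lce1h 21, 20.2 and 23.2, while Rpph1 read 9.37 (62.8), Got1l1 3.61 (22.4), Aldoc 2.65 (20.4) and A2m 0.479 (5.05). In that library fibroblast markers were higher for 29 of 30 (median 2.32) and macrophage markers for 18 of 18 (median 1.81). In DKO+Dnmt3b1 Gstm3 read 0.682 RPKM (19.3 in DKO), Ndufa4l2 2.27 (42.9) and Ly6g6e 1.14 (22.0). Without the low-value filter 30, 30, 121 and 155 genes were called in these 4 comparisons, and the sets tested then included genes below 1 RPKM in every library.

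TKO+Dnmt3a1 against TKO+Dnmt3a2 compares the 2 isoforms of Dnmt3a, and is the only comparison with 2 libraries in each arm. Alg13 was the only gene called: it read 54.3 ± 7.41 RPKM (SD, n = 2) with Dnmt3a1 and 7.08 ± 0.482 with Dnmt3a2, a difference of 2.85 ± 0.16 on the log2 scale (limma, Benjamini-Hochberg adjusted p = 0.0444; 611 genes at an unadjusted p under 0.05). It read 66.0 RPKM in WT, 8.78 in TKO and 47.3 in TKO+Dnmt3b1. Otx2 (7.10 against 0.952 RPKM), A2m (9.55 against 1.78), Lef1 (8.69 against 2.78) and Ly6k (2.23 against 0.503) were higher with Dnmt3a1 without passing. Rhox6 (6.49 against 31.3 RPKM), Rhox9 (4.71 against 19.9) and Neurod1 (0.780 against 3.69) were higher with Dnmt3a2 without passing, and AF357425 and AF357355 were listed at 0 with Dnmt3a1. The call of Alg13 was lost without TKO+Dnmt3a1 replicate 1 (2.71), TKO+Dnmt3a1 replicate 2 (2.99), TKO+Dnmt3a2 replicate 1 (2.78) or TKO+Dnmt3a2 replicate 2 (2.91), and with quantile normalization or median ratio scaling (2.92 in both).

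The enzymes were compared with each other over both families as Dnmt3b1 (2 libraries) against the 2 Dnmt3a isoforms (6 libraries). All 30 fibroblast markers rose with Dnmt3b1 (median 2.46), as did 16 of 18 macrophage markers (median 2.43), and every statement on this comparison stands beside these values. The extracellular matrix gene Tnc rose by 4.36 ± 0.76, the BMP antagonist gene Grem1 by 4.27 ± 0.68, Lce1g by 4.10 ± 0.35, Serpinb2 by 4.07 ± 0.57 and Lyz2 by 4.05 ± 1.15. The largest falls by the naming rule were those of Ndufa4l2 (fell by 2.79 ± 0.75), Aldoc (2.13 ± 0.57 lower), Bnip3 (2.11 ± 0.50 lower), Ddit4 (1.83 ± 0.50 lower) and the synaptonemal complex gene Sycp3, which fell by 1.81 ± 0.30. Of the 18 endoderm genes 12 rose (median 0.93), of the 28 Hox genes 20 rose and 1 fell (median 1.06), and of the 21 genes of the 2-cell-like state 13 rose (median 1.42). Of the 24 naive pluripotency genes 9 fell (median −0.37), with Sox2 at −0.85, Tdgf1 at −0.89 and Esrrb at −0.73, chosen after their values were seen. Limma called 1923 genes higher and 1020 lower (65.3% higher), and 1690 and 1814 (48.2% higher) with quantile normalization. The list tests, which were added after the data were seen, passed by fry at Benjamini-Hochberg adjusted p = 0.00238 (endoderm), 0.0229 (naive), 0.0281 (fibroblast), 0.0329 (Hox) and 0.0495 (2-cell-like), with 0.332, 0.450, 0.625, 0.625 and 0.625 as the adjusted p with an estimated correlation. The macrophage list, also added, had p = 0.000951 by fry over all 10 libraries and p = 0.0882 with an estimated correlation. With the fibroblast mean of each library as a covariate limma called 0 genes in this comparison, and Tnc then stood at 0.09 and Grem1 at 0.60. The count was 77 without TKO+Dnmt3b1, 179 without DKO+Dnmt3b1, 1915 and 1952 without TKO+Dnmt3a1 replicates 1 and 2, and 1861 without DKO+Dnmt3a2. Median, mean and test differed in sign for the mesoderm (−0.22, 0.09, up), Polycomb (−0.13, 0.03, down) and p53 lists (−0.03, 0.14, up).

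TKO family against DKO family, at matched add-back, compares lines without and with Dnmt1 (6 against 4 libraries). The add-back lines had an enzyme put back into TKO or DKO, so that libraries of a family are not independent replicates of Dnmt1 status. The p-values of this comparison hold the spread between lines within the families only. Dnmt1 cannot be told apart from other differences between the 2 families. Dnmt1 fell by 2.78 ± 0.17. Ndufs5 rose by 3.89 ± 0.28 (29.3 against 1.84 RPKM), Ube2l6 by 3.58 ± 0.26 (28.4 against 2.25), the testis cytochrome c gene Cyct by 3.37 ± 0.23 (60.2 against 5.09) and the apolipoprotein gene Apoa2 by 3.33 ± 0.30. Ubd, a ubiquitin-like gene, was listed at 0 in the DKO family and averaged 5.38 RPKM in the TKO family. The Y-linked gene Eif2s3y fell by 4.53 ± 0.32, Rps15a-ps6 on chromosome 11 fell by 3.27 ± 0.20 and the Y-linked Ddx3y fell by 3.15 ± 0.31, while Zfy1 was listed at 0 in every TKO family library. WT read 0.903 RPKM of Ndufs5, 1.14 of Ube2l6 and 10.3 of Rps15a-ps6. Of the 18 endoderm genes 12 rose and 0 fell by limma (median 0.90), with Gata6 (1.34 ± 0.28), Sparc (1.38 ± 0.19) and Cubn (1.5 ± 0.23). Of the 12 mesoderm genes 5 rose (median 0.34), with Hand1 (2.39 ± 0.31), Cdx1 (1.48 ± 0.27) and Eomes (1.20 ± 0.17). The mesoderm median was at percentile 78.04 of matched random lists, whose median was 0.22. With quantile normalization it was 0.11, with 3 members higher and 1 lower. Trophoblast genes rose for 9 of 17 (median 1.02) and X-linked genes for 13 of 20 (median 1.24), and the 2 lists share Rhox6 and Rhox9, as the mesoderm and trophoblast lists share Hand1. Without both Dnmt3b1 libraries 5 X-linked genes were called. The X-linked means of the parents, with 1 library each, were 2.05 in TKO and 2.12 in DKO. In the add-back libraries they were 0.93 to 1.73 in the TKO family and −0.27 to 0.15 in the DKO family. The test of whether the add-back effect differs between the families, given below, did not pass for this list. Of the 19 primed genes 5 fell (median −0.55), with Fgf15 (fell by 2.03 ± 0.24) and Otx2 (fell by 1.74 ± 0.45). By fry the Benjamini-Hochberg adjusted p was 0.00138 for endoderm, 0.00138 for mesoderm, 0.0157 for trophoblast and 0.0415 for both the primed and the X-linked list. With an estimated correlation no call was kept: the adjusted p was 0.399 for endoderm, mesoderm and primed, 0.516 for trophoblast and 0.551 for X-linked genes. The fibroblast markers were higher for 28 of 30 (median 0.50, at percentile 100 of matched random lists, whose median was 0.07) with no called member (Benjamini-Hochberg adjusted p = 0.398 by limma's fry), and 24 of the 30 are measured at 1 RPKM or more in the library that held least of them.

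The other lists did not pass by fry with Benjamini-Hochberg adjustment between the families. The germline list had 10 genes higher and 5 lower (Benjamini-Hochberg adjusted p = 0.248 by limma's fry), with Stra8 up by 2.91 ± 0.31, Tex19.1 by 1.61 ± 0.24 and Sycp3 down at −1.09 ± 0.24. It had 7 higher and 7 lower with quantile normalization, and 7 and 2 without both Dnmt3b1 libraries. The 2-cell-like list had 9 lower (0.112, median −0.83), against 1 without both Dnmt3b1 libraries (median −0.53) and 14 with quantile normalization. The naive list had 4 higher and 4 lower (0.446), with Zfp42 fallen by 2.72 ± 0.18 (43.7 against 292 RPKM) and Dppa3 risen by 0.87 ± 0.10. The imprinted list had 7 higher and 3 lower (0.0854), with Peg3 at 1.59 ± 0.15, H19 at 1.55 ± 0.34 and Magel2 at −1.11 ± 0.22. The Polycomb list had 6 higher and 2 lower (0.112), the interferon list 6 and 1 (0.112), the neural list 1 and 4 (0.536), the p53 list 3 and 0 (0.169), the list of Tet genes, base excision and methyl-CpG readers 2 and 3 (0.845) and the Hox list 1 and 0 (0.353). With quantile normalization, with median ratio scaling or without both Dnmt3b1 libraries, the p53 list had 1 higher and 0 lower. The 2 added lists had 1 higher of 18 macrophage genes (p = 0.408 by fry) and 5 lower of 6 measured Y-linked genes (p = 6.17e-06 by fry, p = 0.00823 with an estimated correlation). List members named here and outside the rule for named genes were chosen after their values were seen. Median, mean and test of the naive list differed in sign (0.05, −0.04, down), and its median was −0.06 with median ratio scaling. In all, limma called 2043 genes higher and 947 lower in the TKO family (68.3% higher; 5354 at an unadjusted p under 0.05), and 590 of the 2990 differed by 1 or more. The median of all genes was 0.107 higher. Quantile normalization gave 1233 higher and 1522 lower (44.8% higher) and median ratio scaling 1465 and 1576 (48.2%), so that the excess of higher genes depended on the scaling. The count was 651 without DKO+Dnmt3a2, 1096 without DKO+Dnmt3a1, 1790 without DKO+Dnmt3b1, 1788 without TKO+Dnmt3b1 and 1817 without TKO+Dnmt3a1 replicate 2. Ndufs5, Ube2l6, Cyct, Ubd, Apoa2, Eif2s3y, Uba1y, Rps15a-ps6, Ddx3y and Zfy1 kept their calls and directions in every alternative that tested them.

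Whether the response to an enzyme put back depends on Dnmt1 was tested as the add-back effect in TKO minus that in DKO. Xlr3c read 9.87 RPKM in TKO and 5.28 on average in its add-back lines, and 21.5 and 0.310 in DKO, a difference of effects of 3.92 ± 0.61. For Cox7b2 the difference was 3.73 ± 0.53, for Xlr3a 3.65 ± 0.58, for Efhc2 3.43 ± 0.39 and for Ephx2 3.38 ± 0.76. On the other side were Spink3 (−2.84 ± 0.62), Zscan4c (−2.76 ± 0.63), Zscan4a (−2.76 ± 0.63), the homeobox gene Gbx2 (−2.61 ± 0.63) and Zscan4d (−2.50 ± 0.94). None passed: limma called 0 genes (1486 at an unadjusted p under 0.05, smallest Benjamini-Hochberg adjusted p 0.346). The X-linked list had a median difference of 1.66 and the 2-cell-like list one of −1.42, and limma's fry gave a Benjamini-Hochberg adjusted p = 0.404 for both, the smallest of the 16 lists. The difference stood beside medians of 1.07 for the fibroblast and 1.08 for the added macrophage list. Limma's fry gave the added list p = 0.0145, in the fit of 9 group means (n = 11 libraries, 2 residual degrees of freedom). Median, mean and test of the primed list differed in sign (−0.22, −0.03, up). Without the low-value filter 66 genes were called.

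Genes that differed in 1 knockout were then followed in the add-back lines of the other, so that no library stood on both sides. Fewer than 20 genes were called in DKO against WT, so the 200 largest rises and 200 largest falls in value were taken. In TKO add-back lines against TKO, the 200 rises had a median of −0.10 (55.0% moved the opposite way, 47.9% in random sets matched on expression), and the 200 falls a median of 0.20 (66.5% opposite, 51.6% in random sets). Among genes with a mean of 1 RPKM or more the median of the 200 rises was −0.03 (52% opposite, 48.9% in random sets), so that their excess was lost, and that of the 200 falls 0.17. Across all genes r was −0.07. The 37 genes that rose in TKO had a median of −0.38 in DKO add-back lines against DKO (64.9% opposite, 52.3% in random sets), and the 12 that fell a median of −0.32 (25% opposite, 48.1% in random sets), so that the falls were not opposed. Genes are not independent replicates, and no p-value is given across them.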

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

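The tests of this part were chosen after the results were seen, except the count of other splits of the samples, which was planned. Among the 143 named genes examined, 13 had one sign in all 5 TKO add-back libraries and the other sign in all 3 DKO add-back libraries, each against its parent. The differences (TKO minus DKO, log2) were positive for Cox7b2 (3.73), Ephx2 (3.38), Otx2 (2.4), Bnipl (1.87), Apoa2 (1.43), Fgf15 (0.86) and Dnmt1 (0.80), and negative for Pramel6 (−2.42), Peg10 (−1.60), C77370 (−1.57), Tet3 (−1.01), Uba1y (−0.94) and Tet1 (−0.59). For Uba1y the TKO side is a sign only, since its changes there were −0.05 to −0.01 at 0.019 RPKM or less, which is no measurable move. The difference itself was tested by limma and called for none of them (smallest Benjamini-Hochberg adjusted p 0.346). Each rests on 1 library per parent, so that an odd value in TKO or DKO moves all libraries of that family alike. Peg10 and Tet3 lie on chromosome 6, whose median deviation was 0.41 in TKO and −0.17 to 0.03 in its add-back libraries. Their smallest falls there were −0.34 and −0.29, so that their shared sign in the TKO family cannot be told apart from this shift.

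Fibroblast and macrophage transcripts were highest in the 2 Dnmt3b1 libraries. For the fibroblast transcripts of TKO+Dnmt3b1, RNA of feeder fibroblasts fits. DKO+Dnmt3b1 could not enter this test, since the DKO family holds Y-linked transcripts itself, so that the source there was not tested. Over the 7 libraries of WT and the TKO family, which have almost no Zfy1 or Uba1y, the Y-linked Eif2s3y followed the fibroblast mean. There r was 0.98 (exact permutation p = 0.000992, n = 7), and 0.90 without TKO+Dnmt3b1 and TKO+Dnmt3a2 replicate 1. A change inside the ES cells that carry Dnmt3b1 cannot be told apart from this, since the fibroblast mean and carrying Dnmt3b1 correlated at 0.85 over the 8 add-back libraries. The 2 libraries of TKO+Dnmt3a2 differed by 0.68 in the fibroblast mean at the same genotype. The source of the macrophage transcripts was not tested.

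In TKO, whole chromosomes stood higher than in WT. Extra copies of whole chromosomes stay open. Chromosomes 6, 11 and 16, picked for their high medians, were each split in the middle. Every part was higher, the smallest by 0.43 on the log2 scale, where 3 copies in place of 2 in all cells would give 0.585. The same 2 libraries raised the explanation, and the limit of 0.2 was set after they were seen. The split therefore shows only that the shift runs along these chromosomes. Chromosomes 12 (0.26 and 0.23) and 3 (0.31 and 0.12) were higher by less, and a part of chromosome 3 stayed under that limit. Scaling by the authors' normalization is argued against, since chromosome medians spread over 0.61 and 1 factor moves all alike. Loss of DNA methylation acting on whole chromosomes stays open: the 2 libraries of TKO+Dnmt3a1 differed by 0.37 on chromosome 11 at 1 genotype, and DKO moved by at most 0.06 on the 3 chromosomes, but DKO keeps Dnmt1. The TKO add-back libraries lacked the shift on chromosomes 6 and 16. Their median deviations were −0.17 to 0.03 and −0.05 to 0.04, against 0.41 and 0.33 in TKO. They differ from TKO both as lines and in the enzyme put back, so that this does not separate extra copies from methylation.

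Y-linked transcripts were near 0 in WT and the TKO family and present in the DKO family. Whether most cells of these lines have no Y chromosome stays open: Zfy1 and Uba1y were at 0.019 RPKM at most in the 7 libraries, but this is the observation that raised the question and no test of it. An exchange of the WT library with one of the TKO family is argued against, since Dnmt1 in WT was 5.74 times the highest value of the TKO family. Of 100 splits of the 10 libraries into 6 and 4 (of 210 possible), 1, the real one, called as many genes as TKO family against DKO family (2990), and the highest other called 1407. The median of the other splits drawn was 0. Each of them mixes the 2 families, so that any difference between the lineages enters its spread and lowers its count. The count therefore sets the real split apart from mixed ones only. It cannot tell Dnmt1 from other differences between the 2 lineages, such as the Y-linked genes.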

How the results depend on the processing

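Leaving out both Dnmt3b1 libraries, the fibroblast covariate, removal of chromosome medians and leaving out chromosomes were chosen after the results were seen, and the other alternatives before the data were examined. All counts are genes called by limma. EdgeR and DESeq2 on counts were not run, since the unit was RPKM and the authors' gene lengths are not in the file. With 9 group means a left-out library leaves 1 residual degree of freedom, and lone libraries are assumed to vary like the replicated ones. Where no reason is given, the cause was not tested. Of 4252 alternative values of 230 results for named genes, 3465 kept direction and call, 586 lost a call, 181 gained one and 20 changed sign. Of the values for counts, lists and reversal, 198 stayed, 105 counts moved by over 1.5 times, 6 list tests became weaker and 6 stronger.

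With a filter of mean 1 RPKM the counts were 115 (TKO against WT, main 49), 3 (TKO+Dnmt3a1, main 0), 39 (TKO+Dnmt3b1, main 0), 142 (DKO+Dnmt3a2, main 4), 368 (DKO+Dnmt3b1, main 0) and 3 (TKO+Dnmt3a1 against TKO+Dnmt3a2, main 1). With no low-value filter they were 71 (DKO against WT), 30 (TKO+Dnmt3a1), 30 (TKO+Dnmt3a2), 121 (TKO+Dnmt3b1), 59 (DKO+Dnmt3a1), 75 (DKO+Dnmt3a2), 155 (DKO+Dnmt3b1), 173 (any add-back, main 559), 66 (add-back effect in TKO against DKO) and 0 (TKO+Dnmt3a1 against TKO+Dnmt3a2); in TKO against WT 59 genes were called, 1 of them among the 49. A pseudocount of 0.1 gave 14 (DKO+Dnmt3a2) and 0 (TKO+Dnmt3a1 against TKO+Dnmt3a2), and a pseudocount of 1 gave 27 (DKO+Dnmt3b1). A log2 change of 1 or more left 178 (any add-back), 590 (families, main 2990) and 1306 (Dnmt3b1 against Dnmt3a, main 2943).

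Quantile normalization gave 0 (TKO against WT), 2 (DKO+Dnmt3a2) and 0 (TKO+Dnmt3a1 against TKO+Dnmt3a2), and turned Tet1 in TKO against WT to −0.06. Median ratio scaling gave 12, 2 and 0 in the same comparisons, and turned Uhrf1 to −0.10 and Tet1 to −0.14 in TKO against WT. A prior without trend gave 0 (TKO against WT), 0 (DKO+Dnmt3a1), 2 (DKO+Dnmt3a2) and 0 (TKO+Dnmt3a1 against TKO+Dnmt3a2). A robust prior gave 77 (TKO against WT), 50 (DKO+Dnmt3a2) and 122 (DKO+Dnmt3b1).

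The additive model over 11 libraries, which lends each comparison the libraries of the other family, gave 319 (TKO against WT), 12 (DKO against WT), 3 (TKO+Dnmt3a1), 19 (TKO+Dnmt3a2), 3467 (TKO+Dnmt3b1 and DKO+Dnmt3b1, the same contrast there), 3 (DKO+Dnmt3a1), 19 (DKO+Dnmt3a2) and 0 (TKO+Dnmt3a1 against TKO+Dnmt3a2). None of the 4 calls in DKO+Dnmt3a1 or in DKO+Dnmt3a2 was among them, so that AF357359, Rian and Lyz2 lost theirs. It turned Tet1 in TKO against WT to −0.20, and in DKO against WT Dnmt1 to −0.23, Tet1 to 0.19 and Tet3 to 0.27. With 9 group means over 11 libraries the counts were 0 (any add-back), 1802 (families) and 1898 (Dnmt3b1 against Dnmt3a), and with each line counted once 2 (any add-back) and 1650 (families).

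With the replicate number as a block (replicate block) the counts were 307 (TKO against WT), 60 (DKO against WT), 7 (TKO+Dnmt3a1), 1002 (TKO+Dnmt3b1), 79 (DKO+Dnmt3a1), 479 (DKO+Dnmt3a2), 1441 (DKO+Dnmt3b1), 6 (TKO+Dnmt3a1 against TKO+Dnmt3a2) and 1 (add-back effect in TKO against DKO). The numbers did not pair: the replicate differences of the 2 lines correlated at r = 0.086 (2 pairs), so these counts are given here only.

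Leaving out 1 library gave from 0 to 0 genes in TKO against WT, 0 to 0 in DKO+Dnmt3a1, 0 to 1 in DKO+Dnmt3a2, 0 to 0 in TKO+Dnmt3a1 against TKO+Dnmt3a2, 0 to 867 in any add-back, 651 to 3245 between families and 77 to 3338 in Dnmt3b1 against Dnmt3a. In any add-back, where each parent is 1 library, it turned the sign without TKO for Dnmt1 (−0.32, highest 0.43, and −0.04 without TKO+Dnmt3b1), Tet1 (0.28, lowest −0.31) and Tet3 (0.43, lowest −0.59), and without DKO for Gbx2 (−0.05, highest 2.63), Dnmt3b (−0.03, highest 1.58), Dnmt3l (−0.17, highest 0.57), Uhrf1 (0.05, lowest −0.15) and Tet2 (−0.27, highest 0.72).

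Without both Dnmt3b1 libraries the counts were 3 (any add-back, with Tet1 at 0.06) and 1794 (families). With the fibroblast mean as a covariate they were 50 (any add-back, with Tet1 at 0.01), 1319 (families) and 0 (Dnmt3b1 against Dnmt3a, with Lyz2 at −2.08), where the covariate holds most of what sets the Dnmt3b1 libraries apart. With chromosome medians removed they were 87 (TKO against WT, 48 of them among the 49), 124 (TKO+Dnmt3b1), 90 (DKO+Dnmt3a2), 335 (DKO+Dnmt3b1) and 355 (any add-back, with Tet3 at 0.12). Without chromosomes 6, 8, 11, 12, 16 and Y they were 1 (DKO+Dnmt3a1), 1 (DKO+Dnmt3a2, Lyz2) and 188 (any add-back), where the imprinted cluster of chromosome 12 is not tested.

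Camera with preset correlation gave adjusted p = 3.28e-11 (2-cell-like), 0.000124 (Hox), 1.04e-07 (X-linked) and 0.0145 (interferon) in any add-back, and 9.25e-09 (2-cell-like), 0.00325 (interferon) and 0.0758 (mesoderm) between families. Camera with estimated correlation gave 0.399 (primed, endoderm, mesoderm), 0.516 (trophoblast) and 0.551 (X-linked) between families. The calls gained with the preset correlation were lost with the estimated one: the adjusted p of camera was 0.894 for all 4 in any add-back, and 0.516 (2-cell-like) and 0.794 (interferon) between families. Taking the 200 largest rises and 200 largest falls in TKO against WT, the medians in the DKO add-back lines were −0.53 and −0.21, and with genes of mean 1 RPKM −0.26 and −0.32.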

Other observations

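Apela, a peptide hormone gene, was at 38.3 RPKM in WT, 39.3 in TKO and 64.9 in DKO, at 33.6 to 37.2 in the 3 DKO add-back lines, and at 5.32 to 11.6 in the 5 TKO add-back libraries. It was not called in TKO+Dnmt3a1 against TKO (limma, Benjamini-Hochberg adjusted p = 0.126), where it and Alg13 had the smallest adjusted p. Alg13 was low in TKO (8.78 RPKM) and in both TKO+Dnmt3a2 libraries (6.74 and 7.42) and at 47.3 RPKM or more in the other 8, TKO+Dnmt3a1 and TKO+Dnmt3b1 among them. Both genes were looked at after their values were seen.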
